A study of Mus musculus with 2 samples.

How the data were processed

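Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in the hindbrain of mouse embryos of the B6NCrl strain at embryonic day 16.5. The design held 1 group of 2 biological replicates, each a pool of male and female embryos. Per the labels, replicate 2 was made from 37 embryos. The number of embryos in replicate 1 was not given in the sources used here.

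The authors deposited peak lists on assembly mm10, per the file headers and the labels. Lists were deposited for each replicate alone and for both replicates together, and the file headers say that they derive from alignment files. The aligner, the peak caller and their versions were not given in the sources used here, nor was the treatment of the Tn5 cutting offset or of duplicate reads. Each deposited list gives a signal value per peak, set by the authors' peak caller, whose scale is not stated and which is used here without a unit. The deposited lists also give the −log10 of each peak's p-value as the authors' caller set it. The deposited ranked lists give a score, −log10 of the irreproducible discovery rate (IDR), a measure of how well peaks keep their rank between 2 sets of reads. The lists thresholded on the IDR were the main lists. Pseudoreplicated lists, replicated lists and a conservative IDR list served as alternatives. The 4 per-replicate columns inside the combined ranked lists were not used, because their names match no replicate's labels. No list gives read counts, so the depth of each replicate is unknown and no counting interval is printed.

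Overlapping entries of a list were merged into regions on the 19 autosomes and the X and Y chromosomes, and a region took the signal value and summit of its strongest entry. Genes were the 21851 protein-coding genes of GENCODE release M21, and sequence came from the GRCm38 assembly, which is mm10. No region of the lists checked ran past a chromosome end, and 8 of 35494 combined regions held unknown bases. A region was called a promoter region when it overlapped 1000 bp on either side of any of 41438 annotated starts. Other regions were called distal and were assigned to the nearest start.

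Replicates were compared by the share of regions that overlapped by 1 bp or more, beside 100 random placements, and by Spearman's rho across shared regions. Regions are not independent replicates, so these comparisons carry no p-value. For each of 22 gene lists, the share of members with a promoter region was tested against all other genes with a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over the lists. The same share was tested by 10000 two-sided permutations of list membership within deciles of promoter CpG count, in a window of 500 bp on either side of a start. Distal regions per gene were compared as list medians by 10000 permutations within deciles of territory, the bases closest to a gene's starts. The random lists were first drawn with replacement and were changed to permutations after the results had been seen. Draws with replacement and with another seed were added as alternatives. Genes or sequence windows, not embryos, are the units of these tests, so the p-values say nothing about variation between embryos. Hox paralogue groups 1 to 5 were compared with groups 9 to 13 by Fisher's exact test and by 100000 permutations.

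Each of 32 binding site consensus sequences was searched within 100 bp on either side of the summits and in flank windows 1000 bp away that lay outside every region. Hits of the consensus at summits and flanks were tested against hits of its reversed, not complemented, sequence with a two-sided Fisher's exact test adjusted over the 32. Where a count was 0, 0.5 was added to each count for the ratio. The SP/KLF consensus is its own reverse, so this test is void for it. Reversal can make or remove a CpG, so 20 shuffles with the same number of CpG steps, or fewer where fewer exist, were added as a control after the data were seen. The replicate difference of a list was the median log2 ratio of replicate 1 to replicate 2 over its regions, centred on all shared regions and set against 10000 random sets of regions.

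The gene lists, the consensus sequences, the tests and most alternatives were fixed before the data were examined. So was the rule for named items: every Hox gene; of each other list, up to 3 members with the highest promoter signal value and up to 3 without a promoter region; the 10 genes with the most distal regions and the 3 with the most among those with a territory under the median; the genes nearest the 10 strongest regions; and every consensus, with values for the 6 largest and 3 smallest summit-to-flank ratios past the threshold of 0.05. The alternatives were other promoter windows, summit windows and flanks, other peak lists, only regions over the median signal value, assignment within 100 kb, and each replicate's own list alone.

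The overlap, the gene list tests, the distal test and the motif test were tested on simulated data, and the Hox comparison, the rank agreement and the replicate difference of lists were not. For the overlap step, 60.1% of 21933 regions were kept and 60.4% were found. All 10 planted gene lists were called by Fisher's exact test and by the matched test, against 10 and 6 of 200 null lists at an unadjusted 0.05. The distal test called 4 of 10 planted lists with 3 times the rate of regions and 2 of 200 null lists, so it is insensitive. A consensus planted in 10.28% of windows was found in 10.28%, and a consensus planted nowhere, with a true ratio of 1, had a ratio of 1.15. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and sequences were aligned with BLAST+ 2.17.0.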

Results

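The data were peak lists from ATAC-seq of embryonic mouse hindbrain, the part of the brain that forms the cerebellum, pons and medulla. At embryonic day 16.5, 2 biological replicates were profiled, and no other tissue or age was compared. The thresholded list of replicate 1 held 58087 peaks in 21933 regions, and that of replicate 2 held 66335 peaks in 26597 regions. The combined list held 90963 peaks in 35494 regions, with a median width of 893 bp and a total of 33.4 Mb, or 1.26% of the genome. The median signal value of these regions was 6.29. The read depth behind the lists is unknown. Coordinates are on mm10.

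Most regions open in the hindbrain of replicate 1 were also open in replicate 2. Of the regions of replicate 1, 19714 (89.9%) overlapped a region of replicate 2, and 19673 (74.0%) of those of replicate 2 overlapped a region of replicate 1. Randomly placed regions overlapped at 2.03% on average and at most at 2.26%. Across 19553 regions of the combined thresholded list that overlapped a region of each replicate, Spearman's rho of the signal values was 0.919. The replicates' values were within 1.5-fold of each other in 96.7% of these regions, without centring. These regions had passed the IDR threshold, which selects for ranks that agree, so the agreement is partly set by that selection. In the pseudoreplicated lists rho was 0.869, with 90.7% within 1.5-fold. Regions without a counterpart were weaker and less often at promoters. In replicate 1 their median signal value was 5.26 against 7.86 for shared regions, and 14.6% against 57.3% were at promoters. In replicate 2 the median was 5.65 against 8.87, with 10.8% against 57.3% at promoters. Of the regions without a counterpart, 95.7% in replicate 1 and 91.3% in replicate 2 lay in the longer, pseudoreplicated list of the other replicate.

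Promoters were the main site of accessible chromatin relative to their share of the genome. Of the combined regions, 36.6% lay at a promoter, against 3.09% of randomly placed regions, a ratio of 11.8. Introns held 26.3% of regions, intergenic sequence 34.8% and exons 2.34%. Promoter regions were also stronger, with a median signal value of 9.33 against 5.48 elsewhere. In total, 13106 of 21851 protein-coding genes had a promoter region. The promoter share was 53.0% in replicate 1 and 45.2% in replicate 2, a mean of 49.1% ± 5.51 (SD, n = 2). It depended on the list, falling to 17.9% in the combined pseudoreplicated list and 18.3% in the replicated list.

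Genes that mark neurons and neural progenitors had open promoters throughout. All 19 pan-neuronal genes had a promoter region in the combined list, against 75.0% of genes in lists with the same promoter CpG content (adjusted p = 0.0029, permutation of list membership). The strongest were Syt1, the calcium sensor of synaptic vesicle release, with a signal value of 17.1 in the combined list and 16.4 and 17.0 in those of replicates 1 and 2 (chromosome 10, 109010283 to 109011776), the synaptic adhesion gene Nrxn1 at 15.2 and the synaptic vesicle gene Syn1 at 11.7. All 18 neural progenitor genes had one as well (adjusted p = 5.5e-04, Fisher's exact test), led by the transcription factor gene Sox9 at 8.41, the intermediate filament gene Vim at 8.23 and Sox1 at 8.15. The progenitor share was not beyond that of CpG-matched genes, at 85.0% (adjusted p = 0.082, permutation of list membership). For regions over the median signal value the progenitor share was 44.4%, against 48.5% of other genes. The direction turned, without a difference past the threshold (adjusted p = 0.94, Fisher's exact test). Nor was the share below CpG-matched lists past the threshold, at 69.4% (adjusted p = 0.081, permutation). With the same restriction the pan-neuronal share was 57.9% (adjusted p = 0.62, Fisher's exact test), against 61.0% in CpG-matched lists (adjusted p = 1.0, permutation). In the replicates' own lists the shares were 94.7% ± 7.44 (SD, n = 2) for pan-neuronal and 91.7% ± 3.93 (SD, n = 2) for progenitor genes.

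Of the gene lists of lineages born in the hindbrain, that of the Purkinje and GABAergic cerebellar lineage passed the test against other genes in the combined thresholded list, where none was above its CpG-matched lists. Of its 22 genes, 19 had a promoter region (86.4%, adjusted p = 0.025, Fisher's exact test), against 87.0% in CpG-matched lists (adjusted p = 1.0, permutation of list membership). Itpr1, the calcium release channel abundant in Purkinje cells, had a signal value of 20.2 (19.5 and 20.1 in the replicates' own lists; chromosome 6, 108212621 to 108213542), Ebf1 had 12.7 and Car8 had 10.7. Skor2, Pcp2 and Prdm13 had no promoter region. This call was lost in each replicate's own list, at 63.6% in replicate 1 and 72.7% in replicate 2 (adjusted p = 0.57 and 0.24, Fisher's exact test), and for regions over the median signal value, at 50% (adjusted p = 1.0, Fisher's exact test). Of 25 genes of the rhombic lip and granule neuron lineage, which supplies the most numerous cerebellar neurons, 20 had a promoter region (adjusted p = 0.058, Fisher's exact test). In the pseudoreplicated and replicated lists 96% had one, which passed against other genes (adjusted p = 0.0023 and 0.0022, Fisher's exact test) and against CpG-matched lists (adjusted p = 0.012 and 0.010, permutation). For regions over the median signal value the share was 36%, below CpG-matched lists at 63.4% (adjusted p = 0.015, permutation). Etv1 at 10.8, Cbln3 at 10.1 and Cbln1 at 9.79 were the strongest, the region of Cbln3 also covering the start of Khnyn, and Barhl1, Nhlh1 and Eomes had none. Of 23 hindbrain regional factors, 16 had one (69.6%, adjusted p = 0.49, Fisher's exact test). Among them were Nkx6-1 at 10.7 (9.15 and 10.9 in the replicates' own lists), Irx2 at 9.90 and Mafb at 9.57, while Gbx2, Pax5 and Phox2a had none. CpG-matched lists had 87.9%, a difference at the edge of the threshold (adjusted p = 0.047, permutation of list membership, and 0.055 with another seed). It was lost with the conservative list (adjusted p = 0.073) and the replicated list (82.6% against 93.0%, adjusted p = 0.23, permutation). In the replicates' own lists it was larger, with 52.2% against 82.6% in that of replicate 1 (adjusted p = 0.0018) and 47.8% against 84.1% in that of replicate 2 (adjusted p = 0.0011, permutation), as it was for regions over the median signal value (30.4% against 72.5%, adjusted p = 0.0011, permutation). Of 18 genes of the brainstem transmitter systems, 9 had one (adjusted p = 0.55, Fisher's exact test), against 72.6% in CpG-matched lists (adjusted p = 0.082, permutation). This difference passed in the lists of replicate 1 (16.7% against 66.1%, adjusted p = 0.0011) and replicate 2 (33.3% against 68.0%, adjusted p = 0.0035), with the 250 bp window (adjusted p = 0.029) and for regions over the median signal value (adjusted p = 0.0011, permutation). Gata3 at 8.42, the serotonin synthesis enzyme gene Tph2 at 6.92 and the motor neuron factor gene Isl1 at 6.72 were open, whereas Slc6a4, Fev and Th had no region in the list. The brainstem share was 16.7% in the list of replicate 1, below other genes (adjusted p = 0.0035, Fisher's exact test).

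Neither glial list differed from other genes past the threshold in the combined thresholded list. The astrocyte share passed with the conservative list (86.7%, adjusted p = 0.049) and with the pseudoreplicated and replicated lists (93.3%, adjusted p = 0.042 in both, Fisher's exact test). Of 15 astrocyte genes, 13 had a promoter region (adjusted p = 0.053, Fisher's exact test), with Aldh1l1 at 11.1, Gfap at 9.43 and Tnc at 7.37, and Aqp4 and S100b had none. Gfap had a promoter region in the list of replicate 1 and not in that of replicate 2. Of 17 oligodendrocyte lineage genes, 9 had one (adjusted p = 0.65, Fisher's exact test). Olig1 at 8.07, Ugt8a at 7.59 and Pdgfra at 6.99 were the strongest, and Sox10, Cspg4 and Nkx2-2 had none.

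Genes of the list of forebrain and midbrain factors had few strong promoter regions in hindbrain. Most members of the list are forebrain genes, so it says little about midbrain factors. Of the 24 genes of the list, 6 had a promoter region (25%, adjusted p = 0.0019, Fisher's exact test), against 84.5% of CpG-matched genes (adjusted p = 0.0022, permutation of list membership, the smallest value that 10000 permutations can give here). The strongest were Arx at 9.20, Lhx2 at 8.14 and Dlx1 at 5.67. Foxg1, Emx1 and Emx2 were without a region in the thresholded list but had weak ones in the pseudoreplicated list, with signal values of 3.76, 3.26 and 2.78. In that longer list 79.2% of the 24 genes had a region and the direction against other genes turned (adjusted p = 0.27, Fisher's exact test), while CpG-matched lists had 90.8% (adjusted p = 0.20, permutation). In the replicated list it was 70.8%, below CpG-matched lists at 90.5% (adjusted p = 0.011, permutation). Their median signal value in the pseudoreplicated list was 3.0, against 9.34 for CpG-matched lists (adjusted p = 0.0015, permutation of list membership). The hindbrain regional factors were also below their CpG-matched lists in the pseudoreplicated list, at 4.64 against 9.34 (adjusted p = 0.0015, permutation of list membership). In these medians genes without a region counted as 0, and they were compared after the promoter shares had been seen.

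Markers of other tissues and of cell types that can be present in dissected hindbrain mostly lacked a promoter region. A promoter region was present for 1 of 11 microglia genes (C1qc at 7.14), 2 of 10 erythroid genes (Gypa at 8.51, Klf1 at 6.35), 2 of 15 liver genes (Apoa1 at 10.6, Apob at 5.55), 1 of 15 skeletal and heart muscle genes (Myh7 at 5.88), 1 of 10 epidermis genes (Krt10 at 7.04) and 1 of 10 germline genes (Dazl at 12.7). Each of these shares was below that of other genes, with adjusted p from 2.8e-04 for muscle to 0.029 for erythroid genes by Fisher's exact test. The erythroid call was lost without replicate 2, at 20% (adjusted p = 0.065, Fisher's exact test). It was also lost for regions over the median signal value, at 20% against 48.5% of other genes (adjusted p = 0.16, Fisher's exact test). Of these 6 lists, muscle (adjusted p = 0.011) and germline (adjusted p = 0.0055) were below CpG-matched lists by permutation of list membership. The muscle call was lost with the pseudoreplicated list (33.3% against 44.3%, adjusted p = 0.78), the replicated list (adjusted p = 0.75) and without replicate 2 (adjusted p = 0.053), and the germline call for regions over the median signal value (adjusted p = 0.071, permutation). Epidermis genes were below CpG-matched lists with the pseudoreplicated list, the replicated list and without replicate 2 (adjusted p = 0.022, 0.026 and 0.018, permutation). The microglia genes Aif1, Csf1r and Cx3cr1, the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, the liver genes Alb, Afp and Apoa2, the muscle genes Myod1, Myf5 and Myog, the keratin genes Krt1, Krt5 and Krt14 and the germline genes Prm1, Prm2 and Tnp1 had none. The endothelial, choroid plexus, and pericyte and meningeal lists did not differ from other genes past the threshold in the combined thresholded list. Endothelial genes had a region in 3 of 10 cases (adjusted p = 0.13, Fisher's exact test), with Kdr at 5.40, Flt1 at 4.46 and Cldn5 at 4.31, and without one at Pecam1, Cdh5 and Tek. In the replicates' own lists the endothelial share was 0% and 10%, below other genes (adjusted p = 0.0014 and 0.0059, Fisher's exact test) and below CpG-matched lists (adjusted p = 0.0011 and 0.016, permutation). Choroid plexus genes had one in 4 of 9 cases (Foxj1 at 8.28, Kl at 6.43, Prlr at 6.41, not Ttr, Folr1 or Kcne2) and pericyte and meningeal genes in 6 of 10 (Col1a1 at 7.08, Foxc1 at 6.75, Tbx18 at 5.45, not Rgs5, Foxs1 or Dcn). Neither share passed Fisher's exact test (adjusted p = 0.55 and 1.0). In the pseudoreplicated list the pericyte and meningeal share was 90% against 56.8% in CpG-matched lists (adjusted p = 0.030, permutation). It did not pass in the replicated list, at 80% against 56.3% (adjusted p = 0.28), or in the combined thresholded list (adjusted p = 0.86, permutation).

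Cell cycle, housekeeping and immediate early genes were open at their promoters. All 14 cell cycle genes, all 20 housekeeping genes and all 12 immediate early genes had a promoter region (adjusted p = 0.0034, 3.0e-04 and 0.0046, Fisher's exact test). The DNA replication gene Mcm3 at 20.4, Ccna2 at 19.9 and Bub1 at 19.5 led the cell cycle list, Vcp at 15.9, B2m at 15.7 and Pgk1 at 15.2 the housekeeping list, and Dusp1 at 13.5, Egr1 at 10.5 and Jun at 10.4 the immediate early list. The region of Dusp1 also covered the start of Ergic1. None of these 3 lists was beyond its CpG-matched share, the lowest adjusted p from permutation of list membership being 0.50, for housekeeping genes. The immediate early call was lost without replicate 1, at 83.3% (adjusted p = 0.12, Fisher's exact test). It was also lost for regions over the median signal value, at 50% against 48.5% of other genes.

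**Figure D1:**
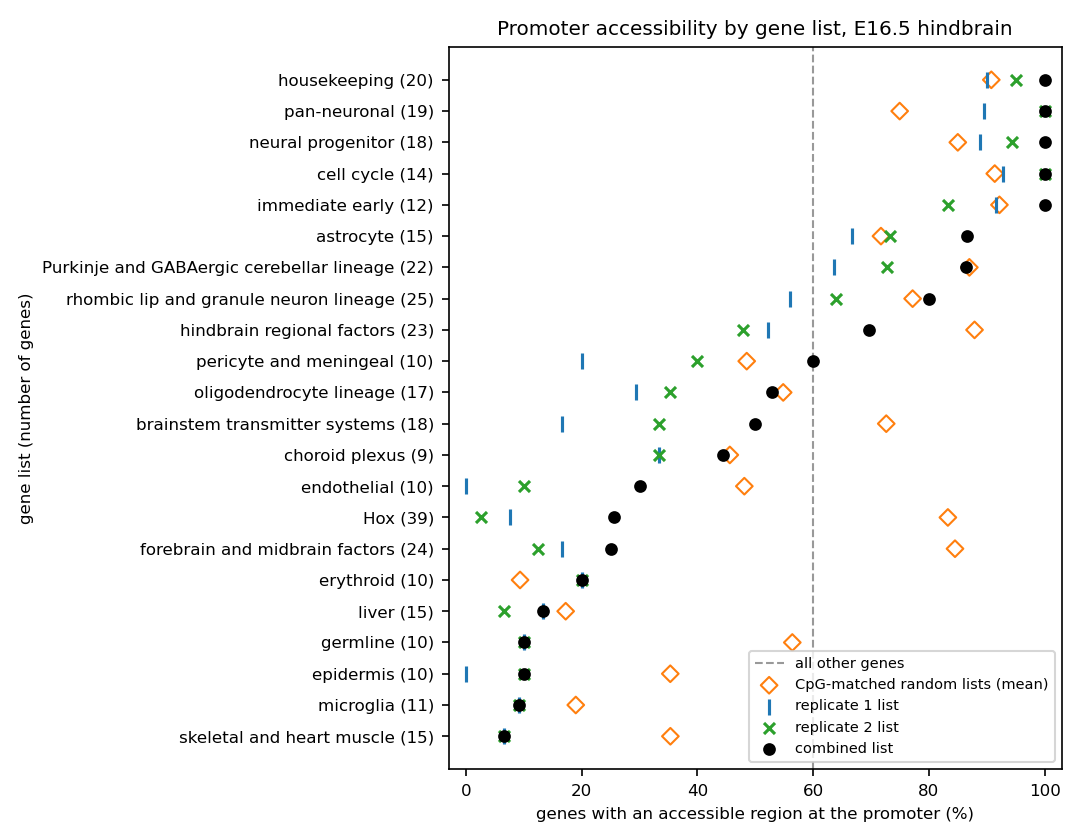
Share of genes of each list with an accessible promoter region, in percent, in the combined thresholded list (black points), in each replicate's own list (bars and crosses) and in CpG-matched random lists (open diamonds); the dashed line marks the other genes. Pan-neuronal genes reached 100% against a matched 75.0%, and forebrain and midbrain factors 25% against 84.5%.

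Distal regions were dense around genes of neural progenitors and astrocytes. Astrocyte genes had a median of 4 distal regions and neural progenitor genes a median of 3, each against 1 in territory-matched lists (adjusted p = 0.040 for both, permutation of list membership). Pan-neuronal genes had a median of 4 against 1 (adjusted p = 0.072, permutation), and oligodendrocyte lineage genes a median of 2 against 0 at the edge of the threshold (adjusted p = 0.047, permutation, and 0.051 with another seed). Sox2, which maintains neural progenitors, had 20 distal regions, Sox9 had 16, the transcription factor gene Nfib had 21 and Nrxn1 had 17, of which Sox9 and Nrxn1 were named after their values were seen. The genes with the most distal regions were Zfp608 with 28 (11 and 12 in the lists of replicates 1 and 2), Nrxn3 with 25 (12 and 17), Auts2, Myt1l and Zfp516 with 23 each, Nfib, Ubash3b and Zfp36l1 with 21 each, and Rapgef5 and Sox2 with 20 each. Among genes with a territory under the median, Ubc had 7, Btn1a1 had 6 and 4930404H24Rik had 5. The progenitor and astrocyte calls were lost with the pseudoreplicated list (adjusted p = 0.24 and 0.16, permutation), where the medians were 6 and 9, with the replicated list (adjusted p = 0.11 and 0.30, permutation) and for regions over the median signal value (adjusted p = 0.76 and 1.0, permutation). The oligodendrocyte call was lost within 100 kb of the start, with a median of 1 (adjusted p = 1.0), for regions over the median signal value (adjusted p = 0.20) and with the replicated list (adjusted p = 0.11, permutation). Within 100 kb pan-neuronal genes passed with a median of 3 (adjusted p = 0.012, permutation). Hindbrain regional factors had a median of 3 against 1 (adjusted p = 0.28, permutation), and passed in the pseudoreplicated list with 14 against 5 (adjusted p = 0.013, permutation) but not in the replicated list (12 against 5, adjusted p = 0.070, permutation). Rhombic lip and Purkinje genes had a median of 3 each (adjusted p = 0.24 and 0.28, permutation). Without replicate 2 the astrocyte median was 2 (adjusted p = 0.10, permutation), and the oligodendrocyte median was 1 without replicate 1 and without replicate 2 (adjusted p = 0.52 and 0.31, permutation).

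The Hox genes, which set position along the body axis and are ordered by paralogue group from head to tail, were accessible at the anterior end of their clusters. Of the 15 genes of groups 1 to 5, 8 had a promoter region (53.3%), against 1 of 16 in groups 9 to 13 (6.25%, p = 0.0059, Fisher's exact test). In the anterior groups, Hoxa1 was the strongest at 6.64 (chromosome 6, 52157940 to 52159637), followed by Hoxc4 at 5.32, Hoxd1 at 5.01, Hoxb4 at 4.91, Hoxa5 at 4.75, Hoxa4 at 4.36, Hoxa2 at 4.13 and Hoxb2 at 3.63. Hoxa3, Hoxb1, Hoxb3, Hoxb5, Hoxc5, Hoxd3 and Hoxd4 had no region in the thresholded list. In groups 6 to 8, Hoxb7 at 3.99 was open, and Hoxa6, Hoxa7, Hoxb6, Hoxb8, Hoxc6, Hoxc8 and Hoxd8 were not in the list. In groups 9 to 13, Hoxb9 at 3.91 was open. Hoxa9, Hoxa10, Hoxa11, Hoxa13, Hoxb13, Hoxc9, Hoxc10, Hoxc11, Hoxc12, Hoxc13, Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13 had none. Hoxb7 and Hoxb9 had no promoter region with the 250 bp window, in the conservative list or in either replicate's own thresholded list. As a whole the 39 Hox genes were below other genes (25.6%, adjusted p = 2.8e-04, Fisher's exact test) and below CpG-matched lists at 83.3%. The anterior against posterior difference was lost in the replicates' own lists, with 3 of 15 against 0 of 16 in that of replicate 1 (p = 0.10, Fisher's exact test) and 1 of 15 against 0 of 16 in that of replicate 2 (p = 0.48, Fisher's exact test). In the pseudoreplicated list it was 14 of 15 against 5 of 16 (p = 6.4e-04, Fisher's exact test), and the Hox list as a whole was not below other genes past the threshold (56.4%, adjusted p = 0.31, Fisher's exact test) but was below CpG-matched lists at 89.8% (adjusted p = 0.0044, permutation).

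**Figure D2:**
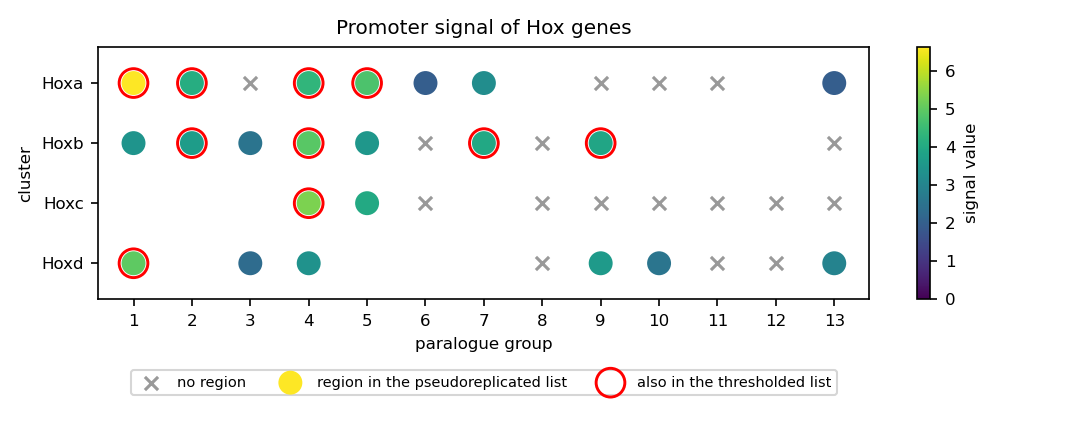
Promoter signal value of the 39 Hox genes by cluster and paralogue group in the combined pseudoreplicated list (filled points), with those also in the thresholded list ringed and those without a region as crosses. Rings mark 8 of 15 genes of groups 1 to 5 and 1 of 16 genes of groups 9 to 13.

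Distal regions carried binding site sequences of the insulator protein CTCF and of neural basic helix-loop-helix factors. The CTCF consensus was within 100 bp of 6.37% of 22508 distal summits and of 0.0813% of flank windows, a ratio of 78.3 (adjusted p = 0.0013, Fisher's exact test against the reversed consensus). The reversed sequence had 0 summit and 2 flank hits, so that p rests on few hits. Against shuffles with the same CpG number, chosen after the data were seen, the CTCF ratio was 28.7 times the shuffled ratio (adjusted p = 3.7e-107, Fisher's exact test). The E-box of Neurod and Atoh1 factors, which drive granule neuron differentiation, was at 11% against 4.29%, a ratio of 2.57 (adjusted p = 4.9e-58, Fisher's exact test). The E-box of Ascl1 and Ptf1a was at 13.3% against 3.95%, a ratio of 3.36 (adjusted p = 0.038, Fisher's exact test). The CREB consensus had a ratio of 5.6 (adjusted p = 1.2e-05), that of ETS 2.72 (adjusted p = 3.7e-06) and that of RBPJ, the Notch effector, 2.10 (adjusted p = 6.1e-04, Fisher's exact test). GATA was depleted at 0.307% against 0.976%, a ratio of 0.314 (adjusted p = 3.7e-06, Fisher's exact test). FOXA and the homeodomain core TAATTA had ratios near 1, at 0.900 and 0.992, and still passed as higher than their reversed sequences, by factors of 1.34 and 1.32. In all, 15 consensus sequences were higher than their reversed form, the others being POU octamer, PBX-MEIS, MEIS, MEF2, ROR, TEAD and NFY, and GATA and EBF were lower. Unlike GATA, EBF was not depleted against flanks, at 0.524% against 0.461%, a ratio of 1.14. NFI, RFX, SOX, HOX-PBX, ZIC, ONECUT, GLI, TCF/LEF, REST, AP-1, NRF1, YY1, HNF4A and HNF1 did not pass against the reversed form, and that test was void for SP/KLF. Against the shuffles, 19 were higher and 1 was lower. RFX (10.2 times the shuffled ratio, adjusted p = 9.1e-120), NFI (4.85, adjusted p = 2.5e-04), HOX-PBX (2.71, adjusted p = 1.4e-39), SP/KLF (2.03, adjusted p = 3.6e-14), SOX (1.26, adjusted p = 0.018) and AP-1 (1.21, adjusted p = 3.4e-05) then passed by Fisher's exact test, and RBPJ, PBX-MEIS and EBF did not. The test against the shuffles does not measure the spread among them. Of 20 shuffles, 3 had a ratio as high as that of ETS, and 2 each as high as those of MEIS, SOX and AP-1. The other sequences higher than their shuffles had 0 or 1 as high. Without replicate 1 the reversed CTCF sequence had no hit, and the call against it was lost (adjusted p = 1.0, Fisher's exact test). The Ascl1/Ptf1a call was lost without replicate 1 and without replicate 2 (adjusted p = 0.21 and 0.45, Fisher's exact test), at 1.96 and 1.72 times the reversed ratio against 2.16 in the combined list, and passed against the shuffles (adjusted p = 2.8e-68, Fisher's exact test). The calls of FOXA (1.16 and 1.32 times, adjusted p = 0.31 and 0.076), PBX-MEIS (2.57 and 7.97 times, adjusted p = 0.33 and 0.25) and ROR (1.66 and 1.43 times, adjusted p = 0.16 and 0.52) were also lost without each replicate by Fisher's exact test. With the 50 bp window 10 were higher and 1 lower. The calls lost there were RBPJ (1.53 times against 1.94, adjusted p = 0.17), POU octamer (3.99 against 4.20, adjusted p = 0.068), Ascl1/Ptf1a (3.13 against 2.16, adjusted p = 0.068), ROR (1.94 against 1.77, adjusted p = 0.068), PBX-MEIS (6.32 against 6.73, adjusted p = 0.19), FOXA (1.28 against 1.34, adjusted p = 0.099) and the lower call of EBF (0.586 against 0.524, adjusted p = 0.068), by Fisher's exact test. RFX passed there (8.35 times, adjusted p = 0.047, Fisher's exact test). PBX-MEIS and ROR were lost with flanks at 2000 bp (adjusted p = 0.18 and 0.17, Fisher's exact test), where others were gained and 15 were again higher. Ascl1/Ptf1a was lost with the conservative list (adjusted p = 0.10, Fisher's exact test). In the pseudoreplicated and replicated lists 20 were higher, with RFX, HOX-PBX, TCF/LEF, AP-1 and HNF4A gained in both, NFI gained in the replicated list and PBX-MEIS lost there (adjusted p = 0.19, Fisher's exact test).

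At promoter summits, 9 consensus sequences were higher than their reversed form and 2 were lower, and of the 9, ONECUT was the 1 that did not pass as higher at distal summits. ETS was at 6.98% of 12986 summits against 0.213% of flanks, a ratio of 32.8 (adjusted p = 7.2e-99), CREB had a ratio of 25.6 (adjusted p = 6.8e-41) and NFY a ratio of 4.01 at 21.8% of summits (adjusted p = 3.0e-175, Fisher's exact test). Ascl1/Ptf1a at 2.10 passed as lower than its reversed sequence, which holds a CpG, and RBPJ at 1.93 passed as higher. Both directions turned against CpG-keeping shuffles, to 1.29 and 0.580 times the shuffled ratio. Both ratios lay within the spread of single shuffles, 4 of 20 being as high for Ascl1/Ptf1a and 15 of 20 for RBPJ. POU octamer at 0.997, MEF2 at 0.362 and FOXA at 0.356 were not enriched over flanks but were higher than their reversed sequences, as were MEIS and ONECUT. TCF/LEF at 0.223 was lower (adjusted p = 1.0e-05), a call lost against the shuffles (adjusted p = 0.68, Fisher's exact test). The POU octamer call was lost without replicate 1, at 2.57 times the reversed ratio (adjusted p = 0.079, Fisher's exact test). The MEF2 call, at 5.68 times, was lost with the conservative list (4.08 times, adjusted p = 0.058), the pseudoreplicated list (2.82, adjusted p = 0.085) and the 50 bp window (12, adjusted p = 0.11, Fisher's exact test), where its reversed sequence had 0 summit hits. With that window FOXA at 2.07 times against 2.67 (adjusted p = 0.062), POU octamer at 3.44 against 3.49 (adjusted p = 0.12) and ONECUT at 1.44 against 1.59 (adjusted p = 0.27, Fisher's exact test) were lost too, and POU octamer with flanks at 2000 bp (2.09, adjusted p = 0.18, Fisher's exact test). The ONECUT call was lost without replicate 1 and without replicate 2, at 1.49 and 1.47 times (adjusted p = 0.071 and 0.076, Fisher's exact test), and against the shuffles, at 1.12 times (adjusted p = 0.56, Fisher's exact test). CTCF, NFI, RFX, the E-box of Neurod and Atoh1, SOX, TAATTA, HOX-PBX, PBX-MEIS, ZIC, EBF, ROR, GLI, TEAD, REST, AP-1, NRF1, YY1, GATA, HNF4A and HNF1 did not pass against the reversed form. NRF1 and YY1 had ratios of 220 and 352 and passed against the shuffles (adjusted p = 2.8e-07 and 2.2e-16, Fisher's exact test), as did SP/KLF at 21.4 (adjusted p = 1.8e-52, Fisher's exact test). PBX-MEIS (9.89 times the shuffled ratio, adjusted p = 1.7e-11), RFX (4.85, adjusted p = 6.1e-22), CTCF (3.13, adjusted p = 7.6e-06) and HOX-PBX (1.68, adjusted p = 0.016) were also higher against the shuffles, and the E-box of Neurod and Atoh1 (0.697, adjusted p = 3.5e-07) and ZIC (0.627, adjusted p = 0.016) were lower, by Fisher's exact test. Of 20 shuffles, 15 were as high as ZIC and 19 as high as the Neurod and Atoh1 E-box. For CTCF and HOX-PBX 1 shuffle each was as high, and for PBX-MEIS and RFX 0. Against the reversed form, NRF1 passed without replicate 1 (20.2 times, adjusted p = 0.0070) and YY1 with flanks at 2000 bp (adjusted p = 0.0055, Fisher's exact test). Without replicate 2, GLI (0.355 times) and the E-box of Neurod and Atoh1 (0.701 times) passed as lower (adjusted p = 0.038 and 0.030, Fisher's exact test).

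**Figure D3:**
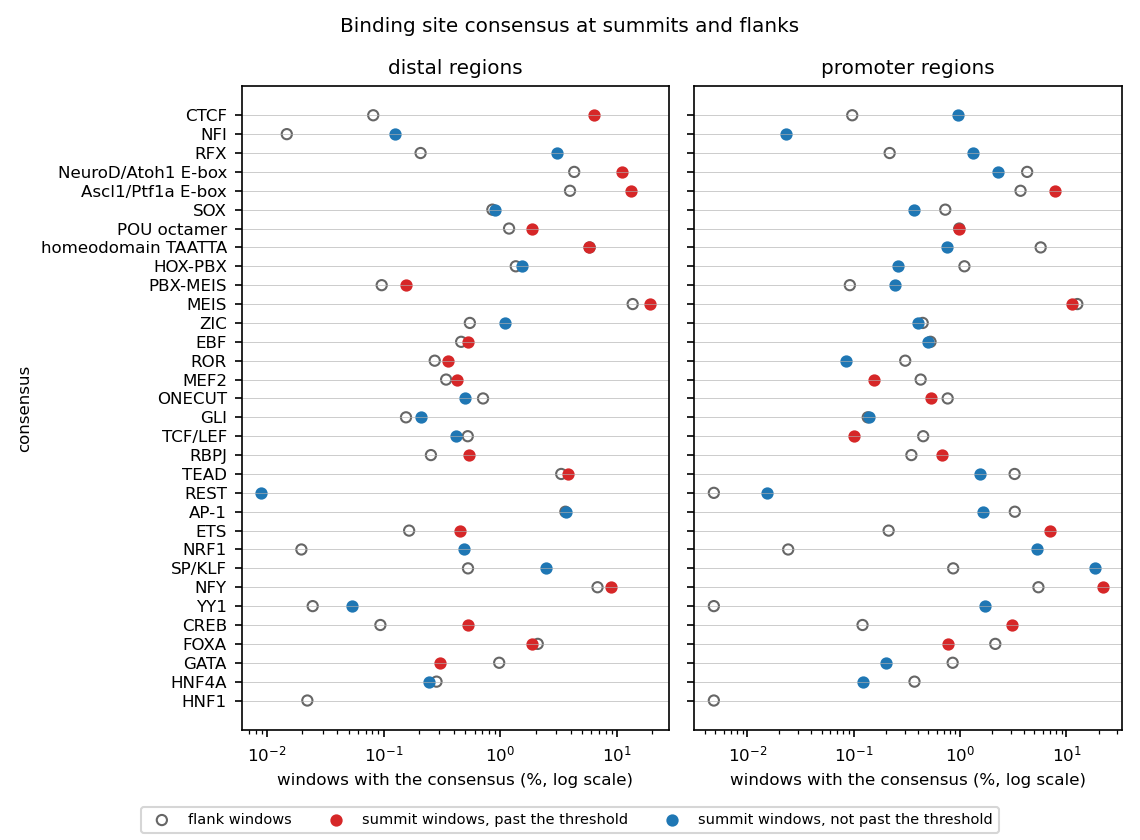
Share of windows with each consensus, in percent on a log scale, at summits (filled, red where past the adjusted threshold) and in flanks (open), for distal and promoter regions of the combined list; shares of 0 are not drawn. CTCF was at 6.37% of distal summits against 0.0813% of flanks, and ETS at 6.98% of promoter summits against 0.213%.

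The 10 regions with the highest signal value were short and lay outside genes, at widths of 246 to 768 bp. The strongest, at 52.8, was on chromosome 2 from 69355469 to 69355735, with Abcb11 as the nearest gene, and the next, at 52.2, was on chromosome X from 143482935 to 143483180 near Pak3. The others were nearest to Frmd4a, G6pd2, Gm5426, Tyrp1, Galc, Myl12b, Gm13283 and 1810024B03Rik. In the lists of replicates 1 and 2 the values were 50.2 and 50.6 for the region near Abcb11 and 50.8 and 48.5 for that near Pak3. Of the 10 regions, 5 matched mitochondrial sequence in part and 4 had another copy in the genome.

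Between the replicates, hindbrain regional factors were the 1 list of 17 outside the central 95% of random sets in signal value, a number close to what chance gives. They had a median log2 ratio of replicate 1 to replicate 2 of -0.08 after centring, over 41 regions, at percentile 1.62 of random sets of regions. On −log10 p they were at -0.28 and percentile 0, and astrocyte genes were also outside, at -0.14 and percentile 0.94. With the pseudoreplicated lists the sign of the hindbrain regional factors turned, at 0.04 and within the random range.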

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

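The tests of depth, of any mitochondrial match and of the regions without such a match, and the comparison of forebrain and midbrain with hindbrain factors, were chosen only after the results were seen. The bound against depth was also moved after its value was seen, from a gain of 2 or fewer promoters to 0 or fewer. Under the first bound the gain of 2 would have counted against depth.

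Signal lay in the ranked lists outside the regions compared. In the ranked list of replicate 1, 133 entries lay on sequences other than the assembled chromosomes, and 183 entries past the IDR threshold were missing from the thresholded list. In replicate 2 these numbers were 102 and 173. The highest signal value among the missing entries was 44.5 in replicate 1 and 43.8 in replicate 2, and no ranked entry was on the mitochondrial genome.

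The 10 regions with the highest signal value lay outside genes and were short. Mitochondrial reads cannot account for all of them: 5 of the 10 had no match to the mitochondrial genome. Their matching length of 0% follows from how these 5 were picked and is no separate support. For the other 5, mitochondrial reads are a candidate source, since 5 of 10 regions against 0 of 200 other intergenic regions had such a match (p = 7.768e-08, two-sided Fisher's exact test), and 4 matched over more than 50% of their length. Sequence present in several copies cannot be told apart from other sources, because 4 of the 10 had another copy in the genome, against 3% of 200 other intergenic regions, and copies missing from the assembly were not searched. Regions on chromosome X near Pak3, on chromosome 2 near Frmd4a and on chromosome 17 near Myl12b had neither kind of match, and no biological explanation was tested.

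Promoters of forebrain and midbrain factors had a region in the longer list in 19 of 24 cases and in the thresholded list in 6. Weak signal is a candidate explanation: genes matched on promoter signal value would give 7.98 passing promoters on average, with a central 95% range of 5 to 11. Peaks of like strength tend to pass the threshold alike, so this match does not separate weak signal from other causes. Depth of the libraries cannot be told apart, because the combined list held 2 more of these promoters than the better replicate, a value the moved bound leaves open, and the depth is unknown. Weaker accessibility of factors of other brain regions may contribute. Their mean signal value in the longer list was 3.10 ± 2.33 (SD over 24 genes), with genes without a region taken as 0. For hindbrain regional factors it was 4.88 ± 3.37 (SD over 23 genes), taken the same way (p = 0.0405, two-sided permutation test, unadjusted). A region was present in 6 of 24 and 16 of 23 in the thresholded list (p = 0.0034, Fisher's exact test). In the longer list it was present in 19 of 24 and 18 of 23 (p = 1.0, Fisher's exact test).

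The promoter share was higher in replicate 1 than in replicate 2 by 7.79 percentage points. Replicate 2 had more regions, and with 20000 regions each the difference was 2.84 points, between the bounds set for and against the number of regions as the cause. It therefore cannot be told apart from other differences between the replicates, and no biological explanation was tested.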

How the results depend on the processing

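The CpG-keeping shuffles, the 20000 strongest regions per replicate, the mean in place of the median, the lists without shared promoters and the redrawn random lists were chosen only after the results were seen. Of the alternatives fixed in advance for the main comparisons, 292 left the call the same and 16 brought a result past the threshold. A further 24 took a result back, 10 moved a value and 3 turned a direction. Among the 10, the alternatives of the rank agreement were counted as moved whatever their value. For gene lists, a turn was counted only where the main or the alternative result was past the threshold. Other turns, such as that of the hindbrain regional factors in each replicate's own list, are among the 292. For the single motifs and the replicate differences by list, 431 were the same, 19 came past the threshold, 30 fell back, 1 moved and 1 turned. Of the added alternatives, 81 left a main result the same, 5 brought it past the threshold, 3 took it back and 3 moved it, and for the single motifs 42 were the same, 14 came past the threshold, 5 fell back and 3 turned. Lists with under 5 regions shared by the replicates had no replicate difference. Read depth is unknown, so what depth limits could not be measured. Where a result changed, the cause was not tested.

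Rank agreement was 0.940 on −log10 p and 0.869 in the pseudoreplicated lists. The promoter share was 17.9% in the pseudoreplicated and 18.3% in the replicated list, 45.2% to 53.0% without each replicate and 51.7% to 54.5% in their 20000 strongest regions. The signal difference of promoters was 4.72 and 4.73 in the longer lists and 2.80 to 3.44 without each replicate.

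For promoters with regions over the median signal value, the share was 50% for Purkinje and immediate early genes. It was 57.9% for pan-neuronal and 20% for erythroid genes, and all of these calls were lost. The share was 16.7% for brainstem transmitter and 0% for endothelial genes, both calls gained as lower. Neural progenitor genes turned direction, at 44.4%. With the conservative list it was 86.7% for astrocyte and 20% for endothelial genes, both calls gained. With the pseudoreplicated list it was 96% for rhombic lip and 93.3% for astrocyte genes, both gained, 79.2% for forebrain and midbrain (turned) and 56.4% for Hox genes (lost). With the replicated list these were 96%, 93.3%, 70.8% (turned) and 51.3%. Without each replicate the share was 63.6% to 72.7% for Purkinje, 0% to 10% for endothelial, 83.3% to 91.7% for immediate early, 16.7% to 33.3% for brainstem transmitter and 20% for erythroid genes. The CpG-matched call of the hindbrain regional factors (adjusted p = 0.047, permutation) was lost with another seed (0.055), with draws with replacement (0.051), and with the conservative (0.073) and replicated (0.23) lists. It passed with the pseudoreplicated list (0.030), the 250 bp window (0.015), over the median signal value (0.0011), and without replicates 1 and 2 (0.0011 and 0.0018).

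The median of distal regions within 100 kb was 3 for pan-neuronal and 1.5 for immediate early genes, both calls gained, and 1 for oligodendrocyte genes, whose call was lost. Over the median signal value it was 1 for progenitor, oligodendrocyte and astrocyte genes, whose calls ended. It was 2 for immediate early genes with the conservative list. With the pseudoreplicated list it was 14 for hindbrain regional factors (gained), 6 for progenitor and 9 for astrocyte genes, and with the replicated list 6.5 for progenitor, 4 for oligodendrocyte and 7 for astrocyte genes, and the progenitor and astrocyte calls ended with both lists and the oligodendrocyte call with the replicated list. Without each replicate it was 1 for oligodendrocyte, 1 to 1.5 for immediate early and 2 to 3 for astrocyte genes. The oligodendrocyte median of 2 fell back with redrawn random lists (adjusted p = 0.056 with replacement and 0.051 with another seed, permutation). Means were 4.13 for hindbrain regional factors, 4.20 for rhombic lip, 5.89 for pan-neuronal, 2.07 for cell cycle and 2.67 for immediate early genes, all past the threshold, and 2.18 for oligodendrocyte genes, which fell back.

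The Hox difference was 6.67 to 20 percentage points without each replicate. The number of consensus sequences higher at distal summits was 10 with the 50 bp window and without replicate 1, 11 without replicate 2 and 20 with the pseudoreplicated and replicated lists, against 15. The calls lost with the 50 bp window were RBPJ, POU octamer, Ascl1/Ptf1a, ROR, PBX-MEIS, FOXA and EBF. The number higher at promoters was 5 with the 50 bp window and 15 against the shuffles, where RFX (4.85), Ascl1/Ptf1a (1.29) and RBPJ (0.580) turned direction. Of these, Ascl1/Ptf1a and RBPJ lay within the spread of single shuffles. The replicate difference of hindbrain regional factors turned to 0.04 (0.0416) in the pseudoreplicated lists.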

Other observations

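The tests in this part were all chosen only after the results were seen.

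Of 110 gene families, grouped by the letters that open the symbol, 5 differed in promoter accessibility from CpG-matched lists past the threshold. Of 110 families with at least 20 genes, the olfactory receptor genes (Olfr) had a promoter region in 2 of 1134 cases, 0.176% against 3.68% in CpG-matched lists. The Rhox homeobox genes had 0 of 34 against 31.3%, the keratin genes (Krt) 4 of 53 against 37.2% and the serine protease genes (Prss) 4 of 39 against 31.4%. The zinc finger genes (Zfp) were higher, with 342 of 394, or 86.8% against 69.3%. Each of these 5 had an adjusted p of 0.022, the smallest that 2000 permutations of membership gave over the 110 families. The permutations took family members as independent genes, and the random lists could hold members of the family itself. How reads that match several copies were treated is not known. A missing region in a family of similar genes therefore need not mean a closed promoter.

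The share of regions past the IDR threshold was set out by −log10 p for regions of several entries and of a single entry, without a test. Between 5 and 10 the shares were 0.0425% and 0.0442%, between 10 and 15 they were 2.71% and 1.79%, between 15 and 20 they were 28.4% and 22.6%, and between 20 and 30 they were 65.9% and 59.3%. Of the entries in the combined thresholded list, 19109 (21%) had a −log10 p under 10. Of the 8326 regions of a single entry in that list, 54 were under 10. Most of the low entries therefore lay in regions of several entries, and a region took the highest −log10 p of its entries.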
